A study of Homo sapiens with 12 samples.

How the data were processed

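Total RNA of human epidermal keratinocytes was hybridised to 12 Affymetrix arrays. Cultures that had not reached confluence were left untreated or received 25 ng/ml of EphB2-Fc or EFNA4-Fc, and RNA was taken at 1, 4, 24 and 48 h. EphB2-Fc and EFNA4-Fc are fusions of a receptor (EphB2) or a ligand (ephrin-A4) with an antibody Fc part, which bind ephrins and Eph receptors on the cell surface. The labels give 1 array for each agent and time, so each agent had 4 arrays and no agent had a replicate within a time. The only control was untreated, and no array with an Fc part alone is listed. Nothing in the labels says whether the cultures were separate or shared a donor. The scan series of the 24 h arrays differed from that of the others, so the 24 h arrays formed a second array batch of 3 arrays and the other 9 arrays formed the first.

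The deposited values are log2 expression levels, 1 per probe set and array. The authors' processing notes name MAS5 and GCOS, the Affymetrix programs for signal calculation and array handling, without versions, parameters or roles. How the log2 step and the scaling between arrays were done is not stated, and the near-equal medians and lower limits are unlike those of plain log2 MAS5 signals. The unit was read from the values themselves, which lay between 2.42 and 13.96 on every array with array medians of 5.69 to 5.76. The plan had assumed linear signals with a pseudocount, so the values were taken as deposited with no pseudocount, and pseudocounts on the back-transformed values were kept as alternatives. For arrays, the number of arrays limits the precision.

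The table held 22277 probe sets, of which 62 were array controls. Probe sets were named from the array's own annotation: 19064 mapped to 1 gene, 1043 to several and 2108 to none. Of the 19064, 19052 were found in the RefSeq gene table. Each of 11963 genes was represented by its probe set with the highest mean log2 level over the 12 arrays. Genes were tested when that mean lay above the median of all probe sets (percentile 50, log2 level 5.73), which left 6801 genes. No coordinates are given.

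Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with trend, two-sided) and Benjamini-Hochberg adjustment over the 6801 genes at 0.05. For the agents, all 12 arrays entered a model with agent and with time point as a block, which also absorbs the array batch, with 6 residual degrees of freedom. The 4 times of an agent stood in as its replicates, so the spread is the variation of the agent difference between times, and a change at 1 time only is not found by this test. A second model gave each agent an early (1 and 4 h) and a late (24 and 48 h) effect, with 2 arrays a side and 4 residual degrees of freedom. The difference late minus early came from the same model. For time in culture, 4, 24 and 48 h were compared with 1 h, with 3 arrays a time, 1 per agent, and agent as the block. The 24 h arrays are the second batch, so for the 24 h comparison batch and time cannot be told apart.

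Before the data were examined, the tests, the rule for named genes and 34 gene lists with 982 genes were fixed. The lists cover keratinocyte layers and junctions, growth and stress programs, signalling pathways, metabolism, RNA and protein turnover, and markers of melanocytes, fibroblasts, and immune and endothelial cells. On the array 836 list genes were present and 673 passed the level filter. Lists with at least 5 tested members were tested, which left 32. The melanocyte list had 3 tested members (MITF, SOX10 and RAB38) and the immune and endothelial list 0. Lists were tested with camera at an inter-gene correlation of 0.01, adjusted over the lists of a contrast; camera compares the members of a list with all other genes. Camera with a correlation estimated from the data and fry, which tests whether a list's members move one way on balance, were alternatives. Counts "adjusted over the list alone" apply the Benjamini-Hochberg adjustment to the tested members of that list.

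Genes were named by rule. In each agent contrast these were the 10 up and 10 down with the largest log2 change among genes past the threshold and of the same sign at all 4 times; places left over were filled from genes with unadjusted p under 0.05, and those genes are said not to pass. In the other contrasts 5 up and 5 down were taken likewise, at each single time 3 up and 3 down, and in each list described up to 4 members with the smallest p. The 10 Eph and ephrin family members tested, of 18 on the array, were listed. XIST, Y-linked genes and probe sets without a symbol were not named. Single times had no test; the median log2 difference of a list was set against 10000 random lists matched on level.

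Further fits used quantile normalization, centring of each array on its median, pseudocounts at 0.25 and 4 times the 25th percentile (5.13 and 82.1), no level filter or one at percentile 75, eBayes without trend, array weights, the mean of a gene's probe sets, all probe sets, only the groups compared, no time block, adjusted p under 0.10, estimated correlation, fry, and leaving out each time or each array. Chosen after the data were seen were a pseudocount at the 25th percentile (20.5), the mean 18S ribosomal RNA control signal of the array as a covariate, and a fit without the 4 arrays whose 18S signal lay more than 1 log2 unit above every untreated array. The agreement of the treatments was compared with 100 simulations in which neither had an effect and both shared the untreated arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

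The model was tested on simulated data of 6801 genes. For EFNA4-Fc against untreated it recovered 99.4% of genes changed 2-fold and 100% of those changed 4-fold, with 4.78% of calls false. For the late EFNA4-Fc effect the shares were 94.2% and 100%, with 5.18% false. For 48 h against 1 h they were 97.6% and 100%. A simulated shift of a list by 0.5 was found in 5 of 5 runs of each. These simulations assume that noise at the 4 times is independent with the spread of the fit, and do not cover an effect that differs between times. The noise was also drawn independently for each gene. They therefore do not test the list calls where genes of a list vary together.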

Results

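The series asks which genes respond when Eph and ephrin signalling between epidermal keratinocytes is engaged from outside with soluble EphB2-Fc or EFNA4-Fc. Expression of 6801 genes was compared over 12 arrays: 4 untreated, 4 with EphB2-Fc and 4 with EFNA4-Fc at 25 ng/ml, each agent with 1 array at 1, 4, 24 and 48 h. The arrays were close to each other, with correlations between 0.894 and 0.995 and medians between 5.69 and 5.76 on the log2 scale. They differed in the signal of the 18S ribosomal RNA control probe sets. Its mean was 6.61 ± 0.61 (SD, n = 4) on untreated arrays, 7.39 ± 1.12 with EFNA4-Fc and 9.16 ± 1.56 with EphB2-Fc. The mean difference from the untreated array of the same time was 2.55 with EphB2-Fc (exact sign-flip test, two-sided p = 0.125, the smallest that 4 times can give) and 0.78 with EFNA4-Fc (p = 0.125). The plot of 18S signal per array shows 4 treated arrays above 8.9, those of EphB2-Fc at 1, 4 and 24 h and of EFNA4-Fc at 4 h.

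**Figure D1:**
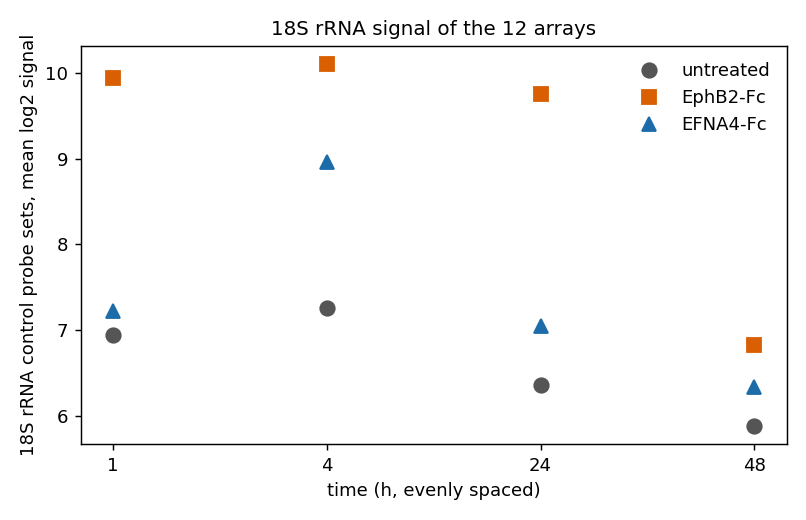
Mean log2 signal of the 18S ribosomal RNA control probe sets on each of the 12 arrays, by hours in culture and agent, 1 point per array. The EphB2-Fc arrays at 1, 4 and 24 h lie at 9.95, 10.11 and 9.76, and the untreated arrays between 5.88 and 7.26.

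Time in culture changed far more genes than either treatment. By 48 h the keratinocytes had raised the genes of the outer epidermis and lowered those of proliferation. Desmoglein 1 (DSG1), a cadherin of differentiated layers, rose by 5.87 ± 0.40 (log2, SE, 3 arrays a time, adjusted p = 8.92e-06). Its partner desmocollin 1 (DSC1) rose by 5.81 ± 0.46, keratin 1 (KRT1), the first keratin of suprabasal cells, by 5.01 ± 0.50, and the cornified envelope precursor SPRR1A by 4.53 ± 0.28. BBOX1, an enzyme of carnitine synthesis, rose by 5.04 ± 0.39. Each time holds an untreated, an EphB2-Fc and an EFNA4-Fc array, so changes with time include part of any late treatment difference. At 48 h KRT1 read 7.55 untreated, 9.65 with EphB2-Fc and 10.28 with EFNA4-Fc. TFPI2, named below, read 6.48, 4.99 and 4.60. The size of the rises also depends on the processing. Over the alternatives DSG1 ran from 3.41 to 6.14, DSC1 from 4.07 to 6.11, KRT1 from 2.77 to 5.61 and BBOX1 from 2.38 to 5.36. DSC1 read 4.63 on the untreated 1 h array, below the level filter of 5.73. The largest falls were in G0S2, an inhibitor of fat breakdown (-3.11 ± 0.23), the protease inhibitor TFPI2 (-2.88 ± 0.30), the sulfotransferase TPST1 (-2.84 ± 0.21), DTL, which controls replication licensing (-2.74 ± 0.24), and the matrix protein THBS2 (-2.52 ± 0.19).

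At 48 h the terminal differentiation list rose with 27 of 27 members past the threshold (mean log2 change 2.92, camera adjusted p = 1.54e-22, adjusted p = 0.378 with an estimated correlation). The antimicrobial peptides rose in 5 of 5 members (mean 2.91, adjusted p = 1.25e-05, 0.378 as adjusted p with an estimated correlation). Examples were S100A8 (3.71 ± 0.24), S100A9 (3.53 ± 0.23), SLPI (3.91 ± 0.33) and PI3 (2.68 ± 0.32); the list shares 3 members with the differentiation list. Desmosome and adherens junction genes rose in 11 of 17 members, 12 adjusted over the list alone, with DSG3 at 1.44 ± 0.11 and PKP1 at 1.70 ± 0.14 (mean 0.70, adjusted p = 5.87e-06, adjusted p = 0.378 with an estimated correlation). DNA replication genes fell in 26 of 27 members (mean -1.19, adjusted p = 4.27e-13, adjusted p = 0.378 with an estimated correlation), among them GINS2 (-2.34 ± 0.15), MCM5 (-1.90 ± 0.13), RRM2 (-2.21 ± 0.18) and TYMS (-1.57 ± 0.12). Cell cycle and mitosis genes fell in 33 of 34 members (mean -1.29, adjusted p = 1.29e-12, adjusted p = 0.521 with an estimated correlation).

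RNA splicing genes fell in 31 of 37 members, 32 adjusted over the list alone, with SFPQ at -1.56 ± 0.13 and HNRNPM at -1.07 ± 0.09 at 48 h (mean -0.56, adjusted p = 2.91e-10, adjusted p = 0.378 with an estimated correlation). Ribosome biogenesis genes fell in 17 of 23, 20 adjusted over the list alone, with nucleolin (NCL) at -0.54 ± 0.08 (mean -0.51, adjusted p = 1.43e-05, adjusted p = 0.521 with an estimated correlation). Of 29 genes of the unfolded protein response, 16 fell and 2 rose, with the chaperone HSPA5 at -1.12 ± 0.13 and SDF2L1 at -1.67 ± 0.11 (mean -0.44, adjusted p = 0.00885, adjusted p = 0.586 with an estimated correlation). Immediate early and AP-1 genes rose in 13 of 23 and fell in 2, with the phosphatase DUSP1 at 3.05 ± 0.30, ATF3 at 1.82 ± 0.22 and ZFP36 at 1.73 ± 0.18 (mean 0.66, adjusted p = 0.000199, adjusted p = 0.521 with an estimated correlation). Of the 10 Eph receptor and ephrin genes tested, of 18 on the array, EFNA3 (1.53 ± 0.16), EPHB3 (0.83 ± 0.11) and EFNA1 (0.34 ± 0.08) rose, EFNB2 fell by 0.36 and 6 did not pass. With the 18S covariate EFNA1 (0.29) and EFNB2 (-0.37) did not pass, nor EFNB2 without the EphB2-Fc 1 h (-0.23), the untreated 48 h (-0.36) or the EFNA4-Fc 48 h array (-0.32). Adjusted over the list alone, 4 rose and 1 fell (mean 0.34, adjusted p = 0.0440, adjusted p = 0.521 with an estimated correlation). In all, 1122 genes rose and 1823 fell at 48 h (limma). With the 18S signal as a covariate 875 passed.

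At 24 h the same lists led. Terminal differentiation genes rose in 23 of 27 members, 24 adjusted over the list alone (mean 1.86, adjusted p = 1.61e-19, adjusted p = 0.615 with an estimated correlation), and antimicrobial peptides in 4 of 5 (mean 1.89, adjusted p = 9.89e-05, same estimated-correlation value), with S100A8 at 3.18 ± 0.24 and S100A9 at 2.78 ± 0.23. Single genes that rose were DSC1 (4.42 ± 0.46), the chloride channel protein CLIC3 (3.67 ± 0.34), DSG1 (3.60 ± 0.40), the serpin SERPINB3 (3.53 ± 0.36) and the cell cycle inhibitor CDKN1C (3.27 ± 0.47). Over the alternatives DSC1 ran from 2.79 to 4.78 and DSG1 from 1.54 to 3.84. DNA replication genes fell in 23 of 27 and rose in 1 (24 and 1 adjusted over the list alone; mean -0.70, adjusted p = 3.06e-11, adjusted p = 0.615 with an estimated correlation). Among them were CDC6 (-1.56 ± 0.19), CDC45 (-1.42 ± 0.14), MCM5 (-1.38 ± 0.13) and MCM7 (-1.24 ± 0.13); TPST1 (-1.97 ± 0.21) and DTL (-1.65 ± 0.24) also fell. Cell cycle genes fell in 13 of 34, 15 adjusted over the list alone (mean -0.48, adjusted p = 2.02e-05, adjusted p = 0.782 with an estimated correlation). Splicing genes fell in 15 of 37 and rose in 1, with SRSF5 at -0.61 ± 0.09 (mean -0.22, adjusted p = 6.59e-05, adjusted p = 0.655 with an estimated correlation).

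Further lists that moved at 24 h were desmosome and adherens junction (9 of 17 up, mean 0.38, adjusted p = 3.05e-05, adjusted p = 0.615 with an estimated correlation) and immediate early and AP-1 (10 up and 1 down of 23, DUSP1 2.19 ± 0.30, mean 0.65, adjusted p = 4.70e-05, adjusted p = 0.655 with an estimated correlation). The unfolded protein response list fell (10 down and 1 up of 29, mean -0.38, adjusted p = 0.00311, adjusted p = 0.756 with an estimated correlation). Ribosome biogenesis fell in 3 of 23 (mean -0.22, adjusted p = 0.0109). Oxidative phosphorylation rose in 9 of 37, with the cytochrome oxidase subunit COX7B at 0.60 ± 0.07 (mean 0.11, adjusted p = 0.00321). These 2 lists had adjusted p = 0.782 with an estimated correlation. Cytosolic ribosome genes rose in 5 of 30 (mean 0.06, adjusted p = 0.0128, adjusted p = 0.788 with an estimated correlation). EFNA3 stood at 0.83 ± 0.16 (adjusted p = 0.00495). At 24 h 674 genes rose and 935 fell. The count was 905 without the EFNA4-Fc 1 h array, 916 without the EphB2-Fc 24 h and 992 without the EFNA4-Fc 24 h array. The 24 h arrays are all of the second batch.

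By 4 h some immediate early, EGF receptor pathway and differentiation genes had risen. The detoxifying enzyme CYP1A1 rose by 3.09 ± 0.52 (adjusted p = 0.0179), the MAPK phosphatase DUSP6 by 1.81 ± 0.25 (adjusted p = 0.00877), the EGF receptor ligand HBEGF by 1.71 ± 0.29, involucrin (IVL) of the cornified envelope by 1.54 ± 0.29 and PHLDA1 by 1.24 ± 0.13. The genes that fell included DNAJB9 (-1.29 ± 0.13) and HERPUD1 (-1.22 ± 0.17) of the endoplasmic reticulum stress response. Others were the signalling regulator RGS2 (-1.40 ± 0.31), ID3 (-1.28 ± 0.22) and the plasminogen activator PLAT (-1.22 ± 0.24). The immediate early and AP-1 list rose in 4 of 23 members and fell in 1, 11 and 2 adjusted over the list alone, with MYC at 0.87 ± 0.10 and JUND at -0.67 ± 0.11 (mean 0.38, adjusted p = 5.67e-09, 0.429 with an estimated correlation). EGFR ligands and MAPK feedback genes rose in 6 of 19, 8 adjusted over the list alone, with SPRY4 at 0.98 ± 0.15 (mean 0.39, adjusted p = 3.38e-05, 0.429 with an estimated correlation). Proteasome genes had a mean of 0.05 with 0 of 27 past the threshold (adjusted p = 0.00173, 0.429 with an estimated correlation). Wound keratin genes rose in 2 of 17 (mean 0.30, adjusted p = 0.00853, 0.429 with an estimated correlation), and NF-kB and cytokine genes rose in 2 of 11 and fell in 1, with IL1A at 0.89 ± 0.14 and IL1B at 0.79 ± 0.12 (mean 0.19, median 0.01, adjusted p = 0.0338, 0.429 with an estimated correlation).

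At the same time terminal differentiation genes rose in 3 of 27 members, 9 adjusted over the list alone (mean 0.52, adjusted p = 3.57e-09, adjusted p = 0.621 with an estimated correlation). The list stood at 0.74 on the untreated and the EFNA4-Fc 4 h array and at 0.08 with EphB2-Fc, and the mean was 0.24 without the untreated 4 h array and 1.07 without the 4 high-18S arrays. Antimicrobial peptides rose in 2 of 5, S100A8 by 1.24 ± 0.24 and S100A9 by 1.19 ± 0.23 (mean 0.66, adjusted p = 0.00173), and heat shock genes fell in 4 of 21, 8 adjusted over the list alone, with FKBP4 at -0.49 ± 0.09 (mean -0.20, adjusted p = 0.0127); both had adjusted p = 0.552 with an estimated correlation. In 3 further lists no member passed while camera did: cell cycle (mean -0.31, adjusted p = 0.0127, adjusted p = 0.969 with an estimated correlation), ribosome biogenesis (mean 0.08, adjusted p = 0.0111) and interferon response (mean 0.06, adjusted p = 0.0127), the last 2 with adjusted p = 0.872 with an estimated correlation. At 4 h 32 genes rose and 94 fell. The count was 598 without the untreated 1 h array and 22 without the 4 arrays of high 18S signal. It was 8 without the EFNA4-Fc and 25 without the EphB2-Fc 1 h array, 29, 38 and 31 without the untreated, EphB2-Fc and EFNA4-Fc 4 h array, 64 and 60 without the untreated and EFNA4-Fc 24 h array, and 47, 56 and 48 without the untreated, EphB2-Fc and EFNA4-Fc 48 h array. Without the 24 h or the 48 h time it was 51 or 34. Without the EFNA4-Fc 1 h array the calls for CYP1A1, DUSP6, HBEGF, IVL, RGS2, ID3, PLAT, HERPUD1, IL1A, IL1B, S100A8, S100A9, SPRY4, FKBP4 and JUND ended, and those for PHLDA1 (highest adjusted p over all alternatives 0.0390) and DNAJB9 (0.0336) held.

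**Figure D2:**
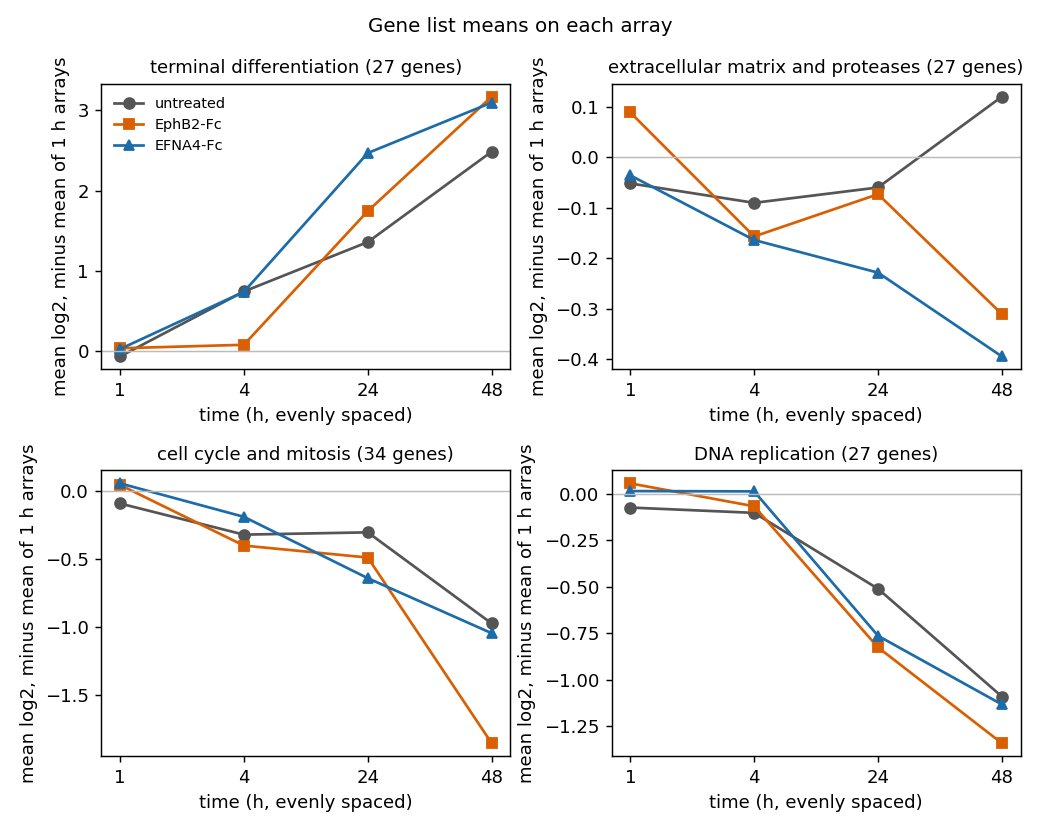
Mean log2 level of the members of 4 gene lists, relative to the mean of the 3 arrays at 1 h, against hours in culture, 1 line per agent and 1 array per point. Terminal differentiation genes climb with time in all 3 agents, by 2.92 on average at 48 h, and DNA replication genes sink by 1.19 on average.

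On the EFNA4-Fc arrays differentiated keratinocyte transcripts had higher values than on the untreated ones, most of it at 24 and 48 h. The list call for these transcripts was lost with an estimated correlation and with fry. In the late contrast, KRT1 was higher by 2.69 ± 0.25 (log2, SE, 2 arrays a side, 6.47-fold, adjusted p = 0.00635), with 2.66 at 24 h and 2.73 at 48 h. The untreated 24 h value of KRT1 was 4.70, below the level filter of 5.73, so the fold rests in part on a low value. TFPI2 fell by 1.53 ± 0.17 (adjusted p = 0.0203), with -1.17 and -1.88 at the 2 times, and SERPINE2, a secreted inhibitor of thrombin and plasminogen activators, fell by 0.90 ± 0.08 (adjusted p = 0.00552), with -0.80 and -0.997. In the late contrast 539 genes had unadjusted p under 0.05 where 340 were expected. The counts lay below 340 for EFNA4-Fc over the 4 times (204) and early (77), for EphB2-Fc early (114) and between the treatments (325). The 3 genes KRT1, TFPI2 and SERPINE2 were all that passed in the late EFNA4-Fc contrast. None of the 3 passed without the EFNA4-Fc 24 h, the EFNA4-Fc 48 h or the untreated 48 h array, or without either late time; without 1 time or array the late count ran from 0 to 27. Omitting the EphB2-Fc 24 h array, the 1 h or the 4 h time, or adding the 18S signal as a covariate, also ended the call for TFPI2. Without the eBayes trend SERPINE2 and TFPI2 lost theirs. Over the alternatives TFPI2 ran from -1.88 to -0.74 and KRT1 from 1.74 to 2.98. Counts were 27 without the EphB2-Fc 1 h or 4 h array, 6 without the untreated 24 h array, 1 without the 24 h time and 0 without the 48 h time. The late count was 73 without the 4 arrays of high 18S signal, none of which is a late EFNA4-Fc array.

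Terminal differentiation genes were higher in the late EFNA4-Fc contrast in 27 of 27 members, with 1 past the threshold and 17 adjusted over the list alone (mean 0.86, camera adjusted p = 2.34e-26, adjusted p = 0.536 with an estimated correlation). The mean was 0.54 without the EFNA4-Fc 24 h array and ran up to 1.18 over the alternatives. Values that did not pass included DSC1 (1.51 ± 0.53), SPRR3 (1.45 ± 0.24) and the kallikreins of corneocyte shedding KLK11 (1.24 ± 0.18) and KLK5 (0.65 ± 0.10). Antimicrobial peptides, 5 of 5 past the threshold adjusted over the list alone and 0 over all genes, had a mean of 0.84 (adjusted p = 1.09e-06), with SLPI at 1.45 ± 0.26 and S100A9 at 0.71 ± 0.21. Extracellular matrix and protease genes were lower in 22 of 27 members, 1 past the threshold and 9 adjusted over the list alone (mean -0.34, adjusted p = 2.81e-07), with the stromelysin MMP10 at -1.69 ± 0.35 and PLAT at -1.05 ± 0.21. Both had adjusted p = 0.536 with an estimated correlation. TGF-beta target genes had a mean of -0.15, 1 past the threshold and 5 adjusted over the list alone, LTBP2 at -0.69 ± 0.12 and SNAI2 at -0.37 ± 0.07 (adjusted p = 0.000420, adjusted p = 0.370 with an estimated correlation), and were the only list that fry called in the late EFNA4-Fc contrast (adjusted p = 0.0493). Outside these lists, genes named by rule included IGFBP3 at 1.77 ± 0.43, the matrix protein POSTN at -1.75 ± 0.24 and DCBLD2 at -1.57 ± 0.37, none past the threshold. POSTN and vimentin (VIM, -1.07 ± 0.16, adjusted p = 0.0587) belong to the fibroblast markers, whose mean of -0.27 camera did not call (adjusted p = 0.103). The extracellular matrix call ended without the untreated 48 h array (mean -0.15).

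Wound keratin genes had a late EFNA4-Fc mean of -0.19 (adjusted p = 0.00261), with 8 down and 1 up adjusted over the list alone and simple epithelial keratins KRT19 at -0.47 ± 0.09 and KRT18 at -0.44 ± 0.09. DNA replication genes had a mean of -0.15 (adjusted p = 0.00136) and desmosome and adherens junction genes 0.14 (adjusted p = 0.00279). The mean was -0.08 for NRF2 genes with 6 down adjusted over the list alone, the metallothionein MT2A at -0.36 ± 0.07 (adjusted p = 0.00961). It was -0.15 for Wnt and Hedgehog genes with DKK1 at -0.65 ± 0.11 (adjusted p = 0.0291), and -0.21 for EGFR and MAPK feedback genes (adjusted p = 0.0365). All these 6 had adjusted p = 0.536 with an estimated correlation. Cell cycle genes had a mean of -0.20 with 32 of 34 negative (adjusted p = 0.00261), cytosolic ribosome genes -0.05 (adjusted p = 0.00986) and interferon response genes 0.11 with IFI6 at 0.61 ± 0.13 (adjusted p = 0.0133), each with adjusted p = 0.733 with an estimated correlation. Basal layer genes had a mean of -0.14 (adjusted p = 0.0133, adjusted p = 0.656 with an estimated correlation) and glycolysis and hypoxia genes 0.07 (adjusted p = 0.0197, adjusted p = 0.579 with an estimated correlation). Without the 24 h time the interferon mean was -0.06, the DNA replication mean -0.04, the desmosome mean 0.02, the EGFR mean -0.08 and the glycolysis mean 0.03, none called. Without the EFNA4-Fc 24 h array the cell cycle mean turned to 0.10 and was called. Without the untreated 48 h array the basal layer mean was 0.01, the Wnt mean -0.06, the wound keratin mean -0.02, the NRF2 mean -0.02 and the cytosolic ribosome mean -0.04, none called.

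Over all 4 times, the EFNA4-Fc difference in terminal differentiation genes had a mean of 0.45 with 27 of 27 positive (adjusted p = 1.50e-18, adjusted p = 0.480 with an estimated correlation). Genes of the same sign at all 4 times included IGFBP3 (1.31 ± 0.33, 4 arrays a side), DSC1 (1.06 ± 0.40), CYP4B1 (0.84 ± 0.31), ZNF750, a transcription factor of epidermal differentiation (0.76 ± 0.29), and KRT13 (0.75 ± 0.28). Antimicrobial peptides had a mean of 0.34 (adjusted p = 0.00249), extracellular matrix genes -0.19 with PLAU at -0.33 ± 0.10 and MMP10 at -0.93 ± 0.33 (adjusted p = 1.75e-05). Interferon genes had a mean of 0.08 (adjusted p = 0.00513), desmosome genes 0.08 (adjusted p = 0.00608) and basal layer genes -0.07 with LAMB3 at -0.33 ± 0.10 (adjusted p = 0.0385). These 5 lists had adjusted p = 0.578 with an estimated correlation. EGFR and MAPK feedback genes had a mean of -0.18 with DUSP6 at -0.54 ± 0.22 (adjusted p = 0.000765), wound keratin genes -0.13 (adjusted p = 0.000765) and TGF-beta targets -0.06 with HMGA2 at -0.49 ± 0.16 (adjusted p = 0.00513), with adjusted p = 0.480 with an estimated correlation. Genes of negative sign at all 4 times included DCBLD2 (-0.87 ± 0.33), TFPI2 (-0.77 ± 0.26, with -0.02 at both 1 and 4 h), G0S2 (-0.75 ± 0.20) and ETV5 (-0.63 ± 0.23). Limma called 0 genes over the 4 times, and 204 had unadjusted p under 0.05 (94 up, 110 down). Of the Eph family, EPHA2 had the largest value, -0.18 ± 0.13. The differentiation mean was 0.23 without the 24 h time, 0.30 without the untreated 24 h and 0.28 without the EFNA4-Fc 24 h array. Without the untreated 48 h array the basal layer mean was -0.00 and the extracellular matrix mean -0.07. Without the 24 h time the antimicrobial mean was 0.12, the TGF-beta mean -0.01, the interferon mean 0.01 and the desmosome mean 0.02, and without the 1 h time the EGFR mean was -0.15 and the wound keratin mean -0.14, none called.

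In the early EFNA4-Fc contrast 0 genes passed in limma and 77 had unadjusted p under 0.05. DNA replication genes had a mean of 0.10 with MCM6 at 0.21 ± 0.13 (adjusted p = 0.000905). Cell cycle genes had a mean of 0.14 with NUSAP1 at 0.31 ± 0.16 (adjusted p = 0.00190), ribosome biogenesis genes -0.11 with NOP16 at -0.31 ± 0.18 (adjusted p = 0.00190) and EGFR and MAPK feedback genes -0.14 (adjusted p = 0.00743). All 4 had adjusted p = 0.991 with an estimated correlation. Single genes that did not pass included VAV3 at 1.49 ± 0.52, the receptor ACKR3 at 1.14 ± 0.50, ZNF750 at 1.13 ± 0.40 and HIRA at -0.80 ± 0.28. Without the 1 h time 2 genes passed. Without the EFNA4-Fc 1 h array 4 passed and the EGFR mean was 0.01. Without the 4 h time the ribosome biogenesis mean was 0.04, the DNA replication mean 0.09 and the cell cycle mean 0.15, none called. With the 18S signal as a covariate the cell cycle mean turned to -0.12 and was called down (adjusted p = 0.000490).

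**Figure D3:**
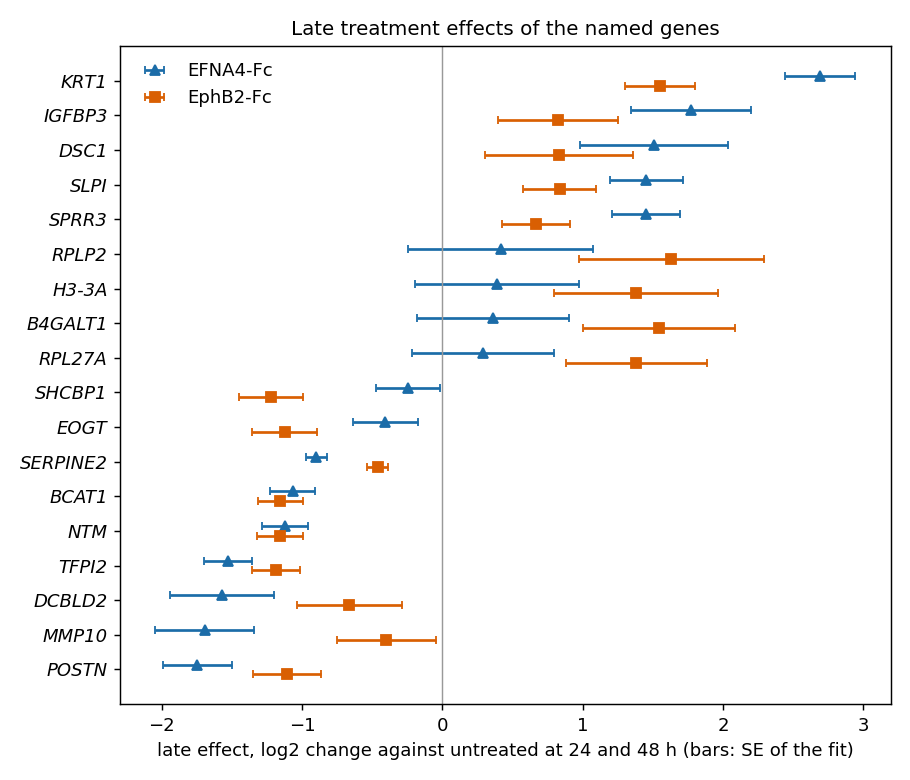
Late (24 and 48 h) log2 difference from untreated of 18 named genes in both treatments, with bars of 1 SE and 2 arrays a side. KRT1 stands highest with EFNA4-Fc at 2.69, TFPI2 lies at -1.53 with EFNA4-Fc and -1.18 with EphB2-Fc, and with EphB2-Fc no gene passed the test.

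With EphB2-Fc, differentiation genes had higher values late in culture, and cell cycle genes lower ones mostly at 48 h (median -0.83, and -0.18 at 24 h, inside the range of random lists). In the late contrast terminal differentiation genes were higher in 26 of 27 members, 0 past the threshold over all genes and 8 adjusted over the list alone (mean 0.54, adjusted p = 7.07e-17, adjusted p = 0.893 with an estimated correlation), with KRT1 at 1.55 ± 0.25 (2 arrays a side, adjusted p = 0.176) and KLK11 at 0.94 ± 0.18. This mean was 0.26 without the EphB2-Fc 48 h array. It was 0.81 without the EphB2-Fc 24 h array or the 4 high-18S arrays, which both leave 48 h as the only late EphB2-Fc array. Antimicrobial peptides had a mean of 0.53, 2 adjusted over the list alone, SLPI at 0.84 ± 0.26 and S100A9 at 0.67 ± 0.21 (adjusted p = 0.000483, 0.893 with an estimated correlation). Cell cycle and mitosis genes were lower in 33 of 34 members, 0 past the threshold (mean -0.53, adjusted p = 1.69e-07, 0.893 with an estimated correlation), with the checkpoint gene MAD2L1 at -0.98 ± 0.24 and the mitotic kinase AURKA at -0.70 ± 0.17. DNA replication genes had a mean of -0.28, 1 down adjusted over the list alone, with RFC3 at -0.67 ± 0.14 (adjusted p = 0.000483, 0.893 with an estimated correlation), and extracellular matrix genes -0.22, 6 down adjusted over the list alone, with SPARC at -0.54 ± 0.11 (adjusted p = 0.0419, 0.893 with an estimated correlation). Desmosome genes had a mean of 0.07 (adjusted p = 0.00317) and glycolysis and hypoxia genes 0.01 (adjusted p = 0.0171), both with adjusted p = 0.893 with an estimated correlation.

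Single genes named in the late EphB2-Fc contrast were B4GALT1, a galactosyltransferase (1.55 ± 0.54), RPLP2 (1.63 ± 0.66) and RPL27A (1.38 ± 0.51) of the ribosome, histone H3-3A (1.38 ± 0.58), SHCBP1 (-1.22 ± 0.23), TFPI2 (-1.18 ± 0.17), NTM (-1.16 ± 0.16), the amino acid transaminase BCAT1 (-1.15 ± 0.16) and EOGT (-1.12 ± 0.23). SERPINE2 stood at -0.46 ± 0.08. The first 4 were high on the 24 h array, which has high 18S signal, and less so at 48 h: B4GALT1 at 2.77 and 0.32, RPLP2 at 3.03 and 0.23, RPL27A at 2.31 and 0.46 and H3-3A at 2.45 and 0.32. On the untreated 24 h array RPLP2 read 5.46, below the level filter of 5.73, and H3-3A 6.19. The cytosolic ribosome list did not rise with them: over 4, 24 and 48 h its EphB2-Fc mean was -0.04, with 0 of 30 members called up. In the late contrast limma called 0 of the named genes or any gene (lowest adjusted p 0.153), while 1046 genes had unadjusted p under 0.05, 239 up and 807 down, around a median of all genes of -0.09. Without the untreated 24 h array the count was 5, without the EphB2-Fc 24 h array 3, and without the 4 arrays of high 18S signal, 1 of them EphB2-Fc at 24 h, it was 39. The cell cycle mean was -0.12 (not called) without the EphB2-Fc 48 h array and -0.95 without the EphB2-Fc 24 h array, and the extracellular matrix mean was -0.01 without the 48 h time, 1 of 9 omissions that ended its call. The desmosome mean was -0.03 and the glycolysis mean 0.00 without the 24 h time, and the antimicrobial mean 0.24 and the DNA replication mean -0.26 without the EphB2-Fc 48 h array, none called.

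Over the 4 times, cell cycle genes had a mean of -0.25 with EphB2-Fc and 32 of 34 negative (adjusted p = 0.000570), with MAD2L1 at -0.48 ± 0.22 and the kinesin KIF20A at -0.46 ± 0.21 (4 arrays a side). Terminal differentiation genes had a mean of 0.13 with 23 of 27 positive (adjusted p = 0.00167), KRT1 at 0.75 ± 0.43 and KLK11 at 0.43 ± 0.22. Both had adjusted p = 0.962 with an estimated correlation. Genes with the same sign at every time included B4GALT1 (1.29 ± 0.36, with 0.02, 2.05, 2.77 and 0.32 at 1, 4, 24 and 48 h), CDC42SE1 (0.81 ± 0.21), the cell surface proteoglycan SDC4 (0.64 ± 0.17), the actin nucleator subunit ARPC4 (0.64 ± 0.18, with 0.05, 1.02, 1.29 and 0.19), CNOT9 (0.59 ± 0.10, another probe set of the gene not of the same sign), TAF9B (-0.91 ± 0.27), BCAT1 (-0.76 ± 0.20), GNA13 (-0.68 ± 0.28) and the checkpoint kinase CHEK1 (-0.57 ± 0.17). With the 18S covariate SDC4 turned to -0.28, and CDC42SE1, ARPC4 and B4GALT1 stood at 0.19, 0.08 and 0.10. Limma called 0 genes (lowest adjusted p 0.551) and 526 had unadjusted p under 0.05, 175 of them up. The Eph receptor EPHB3 stood at 0.19 ± 0.09, the largest Eph family value. Without the 1 h time 368 genes passed, 90 up and 278 down, of which 25 had the same sign at 1 h, and 99 passed without the EphB2-Fc 1 h array. Without the 48 h time the cell cycle mean was -0.04 and the differentiation mean -0.06, and without the untreated 24 h array the latter was -0.03, none called. The differentiation mean was 0.39 without the 4 h time, 0.34 without the untreated 4 h and 0.32 without the EphB2-Fc 4 h array, all called. With the 18S signal as a covariate it was 0.61 and the cell cycle mean -1.05, both called. Without the 4 high-18S arrays these means were 0.68 and -0.89, but only the 48 h EphB2-Fc array is left there. They do not speak for the other times.

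In the early EphB2-Fc contrast terminal differentiation genes had a mean of -0.28 with 24 of 27 negative (adjusted p = 8.35e-08), with SPRR1A at -0.57 ± 0.22 and SPRR1B at -0.68 ± 0.27 (2 arrays a side). DNA replication genes had a mean of 0.08 with the ligase LIG1 at 0.29 ± 0.14 (adjusted p = 0.00505), and both had adjusted p = 0.924 with an estimated correlation. Both early EphB2-Fc arrays had high 18S signal, 3.00 and 2.85 above the untreated arrays, and with that signal as a covariate the differentiation mean was -0.03. Single genes of the same sign at both times included the actin-binding protein CTTN (0.83 ± 0.32, and -0.45 with the 18S covariate), CNOT9 (0.73 ± 0.14), CSPG4 (0.52 ± 0.18), the amino acid transporter subunit SLC7A8 (-1.46 ± 0.53, with -2.68 at 1 h and -0.24 at 4 h, and 2 of 4 other probe sets of the same sign), TAF9B (-1.03 ± 0.22) and the glucocorticoid receptor co-chaperone FKBP5 (-0.996 ± 0.26). SLC7A8, TAF9B and FKBP5 were lowest on the 1 h array (TAF9B -1.46, FKBP5 -1.60), which has the highest beta-actin (0.351) and GAPDH (0.380) 3′ minus 5′ signals of the 12. Limma called 0 genes, 114 had unadjusted p under 0.05, without the EphB2-Fc 4 h array 6 passed and without the 4 h time 1. The differentiation mean was 0.10 without the 4 h time and the DNA replication mean 0.04 without the 1 h time, neither called. For CHP1 (0.46 ± 0.16) another probe set of the gene did not share the sign.

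The test of the difference between the treatments called 0 genes in limma (lowest adjusted p 0.772, 325 with unadjusted p under 0.05). As groups, terminal differentiation genes were lower with EphB2-Fc than with EFNA4-Fc in 25 of 27 members (mean -0.32, adjusted p = 0.00129), with DSC1 at -0.97 ± 0.40 and CALML5 at -0.41 ± 0.16 (4 arrays a side). Cell cycle genes were lower in 33 of 34 (mean -0.22, adjusted p = 0.00168), with ASPM at -0.48 ± 0.20 and ZWINT at -0.23 ± 0.09. Interferon response genes had a mean of -0.13 with 27 of 31 negative and IFIT3 at -0.36 ± 0.13 (adjusted p = 0.0109), and extracellular matrix genes 0.09 with MMP10 at 0.72 ± 0.33 and PLAU at 0.28 ± 0.10 (adjusted p = 0.00212). Immediate early genes had a mean of 0.02 and a median of 0.01, near 0 (adjusted p = 0.0405). These 5 had adjusted p = 0.998 with an estimated correlation. EGFR and MAPK feedback genes had a mean of 0.09 (adjusted p = 0.00212), wound keratin genes 0.07 (adjusted p = 0.00561) and NF-kB genes 0.05 (adjusted p = 0.0405), with adjusted p = 0.786 with an estimated correlation. KRT1 differed by -0.60 and did not pass.

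Single genes that differed in the same direction at all times, none past the threshold, included IGFBP3, which binds insulin-like growth factors (-1.08 ± 0.33), the chaperone calreticulin (CALR, 0.65 ± 0.27, with 1 of 2 other probe sets of the same sign), CTTN (0.63 ± 0.21), the transglutaminase TGM2 (0.55 ± 0.18), DIXDC1 (-0.51 ± 0.19) and the mitotic kinase NEK2 (-0.49 ± 0.22). With the 18S signal as a covariate the terminal differentiation mean was 0.01, the extracellular matrix mean -0.11 and CTTN -0.10. Without the 4 high-18S arrays EphB2-Fc keeps only its 48 h array. The differentiation mean then turned to 0.08, with DSC1 at 0.01. Without the EphB2-Fc 1 h array 13 genes passed; without the 1 h time, or without that array, 0 lists moved. Without the EphB2-Fc 48 h array the cell cycle mean was -0.02, without the EFNA4-Fc 24 h array the differentiation mean was -0.15, neither called, and without the EFNA4-Fc 48 h array 5 lists moved.

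The late effect of each treatment differed from its early effect in several groups. With EphB2-Fc the terminal differentiation mean was 0.82 higher late than early (adjusted p = 7.94e-26) with 27 of 27 positive and 8 adjusted over the list alone, antimicrobial peptides 0.78 (adjusted p = 1.04e-05), and DNA replication genes -0.37 with POLA2 at -0.77 ± 0.20 (adjusted p = 4.40e-07), each with adjusted p = 0.537 with an estimated correlation. Cell cycle genes were at -0.56 with AURKA at -0.77 ± 0.25 (adjusted p = 4.16e-08) and extracellular matrix genes at -0.26 (adjusted p = 0.00224), with adjusted p = 0.774 with an estimated correlation. Desmosome genes were at 0.14 with DSG3 at 0.53 ± 0.10 (adjusted p = 8.45e-05), glycolysis genes at 0.05 (adjusted p = 0.00224) and Wnt and Hedgehog genes at -0.32 with DKK1 at -0.72 ± 0.16 (adjusted p = 0.0157), with adjusted p = 0.656 with an estimated correlation. Single values included KRT1 (1.60 ± 0.35), CXCL14 (1.42 ± 0.56), SPRR1A (1.25 ± 0.31), SHCBP1 (-1.33 ± 0.32) and HDAC9 (-1.28 ± 0.30), and limma called 0 genes (403 with unadjusted p under 0.05; 2 called without the EphB2-Fc 4 h array). The differentiation mean was 0.43 without the 4 h time, 0.46 without the EphB2-Fc 4 h and 0.54 without the EphB2-Fc 48 h array. Without the EphB2-Fc 48 h array the cell cycle mean was -0.15, and without the 4 h time the extracellular matrix mean was -0.36, the Wnt mean -0.38 and the glycolysis mean -0.06, none called.

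With EFNA4-Fc, terminal differentiation genes were 0.82 higher late than early (adjusted p = 9.13e-19), 10 adjusted over the list alone, antimicrobial peptides 1.00 (adjusted p = 3.20e-06) and DNA replication genes -0.25 (adjusted p = 7.25e-06), each with adjusted p = 0.661 with an estimated correlation. Extracellular matrix genes were at -0.31 (adjusted p = 2.63e-05), cell cycle genes at -0.34 (adjusted p = 2.98e-05), cytosolic ribosome genes at -0.07 with RPS3 at -0.22 ± 0.08 (adjusted p = 0.00142). NRF2 genes were at -0.12 (adjusted p = 0.0158), glycolysis genes at 0.09 with hexokinase HK2 at 0.53 ± 0.16 (adjusted p = 0.0233), ribosome biogenesis genes at 0.16 (adjusted p = 0.0238) and desmosome genes at 0.12 (adjusted p = 0.0433). These 7 lists had adjusted p = 0.687 with an estimated correlation. TGF-beta targets were at -0.17 (adjusted p = 0.00256, adjusted p = 0.631 with an estimated correlation). KRT1 (2.69 ± 0.35), SPRR3 (1.57 ± 0.34), TGM1 (1.26 ± 0.31), POSTN (-1.91 ± 0.35) and MMP10 (-1.53 ± 0.50) were among the genes named, and SERPINE2, at -0.95 ± 0.11, had the lowest adjusted p, 0.0614. Limma called 0 genes and 346 had unadjusted p under 0.05. The differentiation mean was 0.49 without the EFNA4-Fc 24 h array. Without the 1 h time, the untreated 24 h or the EphB2-Fc 48 h array 2 genes passed, and 1 without the 24 h time or the EphB2-Fc 24 h array. Without the 4 h time the TGF-beta mean was -0.10, the glycolysis mean 0.06, the ribosome biogenesis mean 0.01 and the NRF2 mean -0.06. Without the untreated 48 h array the extracellular matrix mean was -0.12, none of these called. The cell cycle mean was -0.04 without the EFNA4-Fc 24 h array and the desmosome mean -0.01 without the 24 h time.

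At single times, with 1 array a side and no test, differentiation genes had a median of -0.66 with EphB2-Fc at 4 h, with DSC1 at -1.85. At 24 h the medians were 0.42 with EphB2-Fc and 1.02 with EFNA4-Fc, and at 48 h 0.58 and 0.49; these 4 late medians lay above all of the random lists. At 48 h with EphB2-Fc cell cycle genes had a median of -0.83, below all random lists, with BUB1 at -1.84 and CEP55 at -1.46. At 4 h with EFNA4-Fc immediate early genes had a median of 0.41, with EGR1, an early growth response transcription factor, at 2.58, VAV3 at 2.70 and CYP1A1 at 2.90. That array had an 18S signal 1.71 above untreated and a beta-actin 3′ minus 5′ value of -0.28, apart from the other EFNA4-Fc arrays. At 1 h the same list had a median of -0.22 with IER3 at -1.12 and DUSP6 at -0.91. The glutathione-degrading enzyme CHAC1 stood at 2.30 with EphB2-Fc and 2.55 with EFNA4-Fc at 48 h, when MMP1 was at -2.06 and MMP10 at -2.55 with EFNA4-Fc. The median of all genes was 0.10, -0.10, -0.12 and -0.06 with EphB2-Fc at 1, 4, 24 and 48 h, so EphB2-Fc values at 1, 4 and 24 h carry a shift of about that size. Genes past 2-fold numbered 15, 28, 67 and 48 with EphB2-Fc and 2, 36, 72 and 28 with EFNA4-Fc, and 32, 122 and 213 between neighbouring untreated times. With a pseudocount of 82.1 they numbered 2, 8, 13 and 6, and 1, 11, 24 and 11.

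The effects of both treatments over the 4 times correlated across genes with r = 0.494, where genes are not independent replicates. Effects that share untreated arrays correlate even when neither exists: the simulated r averaged 0.502, with 95% of values between 0.480 and 0.526. The covariance was 0.00973 against a simulated 0.00745 (0.00695 to 0.00804). With the untreated arrays divided by time between the treatments, r ran from -0.163 to 0.322 over 6 ways. The late effects, over 24 and 48 h, correlated with r = 0.608 when they shared untreated arrays. Without shared arrays each effect came from a single time. That r was 0.128 for EphB2-Fc at 24 h against EFNA4-Fc at 48 h, and 0.427 for EphB2-Fc at 48 h against EFNA4-Fc at 24 h. These values also differ in time and number of arrays, so the fall is not due to the untreated arrays alone. The r over the 4 times was 0.729 without the untreated 1 h array, 0.348 without the EphB2-Fc 1 h and 0.342 without the untreated 24 h array. It was 0.343 without the EphB2-Fc 48 h array and 0.341 without the 48 h time.

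Among the lists for which no contrast gave a call were tight and gap junction (lowest adjusted p 0.181), Notch pathway (0.291), cholesterol and sterol synthesis (0.151), fatty acid and ceramide lipids (0.0539, at 48 h, mean 0.25), p53 targets (0.158), apoptosis regulators (0.372) and fibroblast markers (0.0567, early EphB2-Fc, mean -0.10). The 3 tested melanocyte genes MITF, SOX10 and RAB38 had late EFNA4-Fc values of 0.13, 0.21 and 0.20, with the lowest adjusted p 0.861, and no immune or endothelial marker passed the level filter.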

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

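The tests against an exchange of arrays, RNA quality, a low untreated array or batch, and 18S signal were chosen after the results were seen, and those of spread of values and of time in culture before.

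The first pattern is the late rise of terminal differentiation genes in both treatments, stronger than in untreated cells at the same hours. A low untreated array at 24 h or the batch of the 24 h arrays cannot be told apart from a response: at 48 h, in the other batch, the lower of the 2 list medians was 0.49, but both share 1 untreated array, and the spread between cultures is not known. An 18S signal more than 1 log2 unit above every untreated array is not needed for the rise. The lowest median on the 3 late treated arrays under that cut, at 2 times, was also 0.49. Their 18S signal was still above untreated, by 0.95 (EphB2-Fc 48 h), 0.69 (EFNA4-Fc 24 h) and 0.45 (EFNA4-Fc 48 h). A part of such a smaller excess can therefore not be excluded. Across genes, the late effect of each treatment correlated with the 48 h minus 1 h change of the other treatment, with the lower r at 0.487. Treated cultures that may be further along the same course in culture fit the values. That change includes the other treatment's own 48 h effect, so a response shared by both agents would give a positive r too. Whether the agents speed differentiation or the cultures were denser or older at the start cannot be decided, since the labels give no cell density and nothing separates cultures from agents, and the agent as a cause stays open. No array with an Fc part alone is listed. An effect of Fc or of added protein can therefore not be told apart from Eph and ephrin signalling.

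The second pattern is 10 genes at least 2-fold higher with EphB2-Fc at both 4 and 24 h. If genes passed independently on the 2 arrays, 0.0412 would be expected. Both arrays have high 18S signal, so independence is not given and the excess does not measure chance. The 10 genes are ARPC4, AXL, B4GALT1, CALR, CDC42SE1, CTTN, FKBP9, H3-3A, RPL27A and RPLP2, chosen after their values were seen. Their medians were 1.34 and 1.69 at the 2 times, and 0.59 and 0.47 with EFNA4-Fc. Carry-over of 18S RNA into the labelled material cannot be told apart from a response: the EphB2-Fc 1 h array has as high an 18S signal (3.00 above untreated) and a median of 0.0348 for these genes, but it is 1 array. With the 18S signal as a covariate the median difference of the 10 genes over the 4 times went from 0.79 to 0.0871, with 6 of 10 positive. That fall decides nothing, since the 18S signal was itself 2.55 higher on average with EphB2-Fc and the covariate can take up a response as well. A narrower spread of values on the EphB2-Fc arrays is argued against by quantile normalization, after which the lower median was 1.42. A response to EphB2-Fc that is over by 48 h, when the median was 0.20, stays open, as does another fault of these 2 arrays, which was not tested.

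The third pattern is the EphB2-Fc difference at 1 h, which ran opposite to the mean of the other times across genes (r = -0.451). A different spread of values is argued against by quantile normalization, which left r at -0.438. RNA quality stays possible, since the beta-actin 3′ minus 5′ signal of this array, 0.351, and its GAPDH signal, 0.380, were the highest of the 12. A highest rank alone does not show that it gave the opposite values. The next highest GAPDH signal, 0.270, was on the EphB2-Fc 4 h array, whose difference had r = 0.319 with the mean of the other times. An exchange of the untreated and EphB2-Fc arrays at 1 h cannot be told apart from the labels as given: the 18S signal of 9.95 on the array labelled EphB2-Fc is like that of other EphB2-Fc arrays, but 1 EFNA4-Fc array shows high signal as well. An early response of the cells opposite to the later one stays open as the biological reading, since the labels list only 1 array per agent at 1 h.

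The 18S control signal stood above the untreated array of its time by 3.00 and 2.85 with EphB2-Fc at 1 and 4 h, by 3.40 at 24 h and by 1.71 with EFNA4-Fc at 4 h. With EphB2-Fc at 48 h it was 6.83, far below the other EphB2-Fc arrays (9.76 to 10.11). Of the 4 arrays with high signal 3 are in the first batch and 1 in the second. Their beta-actin 3′ minus 5′ values ran from -0.29 to 0.35 and those of the other 8 from -0.24 to -0.06. Their GAPDH values ran from 0.136 to 0.380 and those of the other 8 from 0.0447 to 0.173. These comparisons were chosen after the signal was seen. Among 91 groups of 4 arrays, 11 had an array far from the other 3, where chance gives about 1 in 20 groups, or 4.55. The beta-actin 3′ minus 5′ value of the untreated 48 h array was -0.0942, apart from -0.24 to -0.22 on the others, and that of EFNA4-Fc at 4 h was -0.28, apart from -0.11 to -0.09. In 5 genes the EphB2-Fc difference at 1 h stood apart: TFAP4 0.19, GNA13 -1.43, TMEM259 -1.55, GTF2I -1.33 and SCYL2 -1.44. The EFNA4-Fc difference of the basal layer list was -0.24 at 48 h and that of the desmosome list 0.26 at 24 h. ID3 differed between the treatments by -1.43 at 4 h and by -0.16 to -0.04 at the other times.

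By a test of the difference itself, 19 list effects differed between early and late. With EphB2-Fc these were terminal differentiation (0.82), antimicrobial peptides (0.78), desmosome (0.14), glycolysis and hypoxia (0.0532), cell cycle and mitosis (-0.56), DNA replication (-0.37), Wnt and Hedgehog (-0.32) and extracellular matrix (-0.26). With EFNA4-Fc these were terminal differentiation (0.82), antimicrobial peptides (1.00), ribosome biogenesis (0.16), desmosome (0.12), glycolysis and hypoxia (0.0859), cell cycle (-0.34), extracellular matrix (-0.31), DNA replication (-0.25), TGF-beta targets (-0.17), NRF2 (-0.12) and cytosolic ribosome (-0.0716). None of the 19 held with an estimated correlation.

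Other splits of the same arrays were counted for each comparison of at least 3 arrays a side. For EphB2-Fc and EFNA4-Fc against untreated and EphB2-Fc against EFNA4-Fc the real count of genes was 0, which all 35 of 35 splits reach by construction, so this count decides nothing; the highest other split gave 1101, 4 and 121. At unadjusted p under 0.05, chance cannot be excluded: 10, 19 and 13 of 35 splits gave as many genes as the real 526, 204 and 325, with 2206, 1317 and 1794 in the highest other. The split with 1101 genes exchanges the untreated and the EphB2-Fc 1 h array, and beside a real count of 0 it points to a structure of the samples. Chance cannot be excluded for the lists either: 32, 18 and 16 of 35 splits gave as many lists as the real 2, 9 and 8, and the highest other splits gave 15, 19 and 15. Most of these splits put both arrays of a time on 1 side. Of the 8 that keep each time on both sides, too few for a share under 0.05, 7, 6 and 2 gave as many lists, with 14, 19 and 9 in the highest other, and for genes the highest other gave 1101, 0 and 1. At unadjusted p under 0.05, 3, 4 and 4 of these 8 gave as many genes as the real split. For 4, 24 and 48 h against 1 h, 10 splits are too few for a share under 0.05. The real counts were 126, 1609 and 2945 genes, reached by 1 of 10 splits each, with 0 in the highest other, and 11, 11 and 10 lists, reached by 2, 2 and 3, with 12 in the highest other.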

How the results depend on the processing

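The 18S covariate, the fit without the 4 arrays of high 18S signal and the pseudocount at the 25th percentile were chosen after the data were seen; all other alternatives were planned. With 1 array per agent and time, omission of 1 array can leave a stage with 1 array, which is then assumed to vary like the others. The fit without the 4 high-18S arrays leaves EphB2-Fc only its 48 h array and the 4 h time only its untreated array. The 18S signal was higher with EphB2-Fc, by 2.55 on average. A fit with it as a covariate can therefore also take up an EphB2-Fc effect. Of the results for named genes under 32 alternatives, 7639 kept direction and side of the threshold, 130 lost the call, 140 gained one and 10 reversed. For lists 2545 kept it, 511 lost the call and 27 reversed. For counts and r, 624 stayed within 1.5 times or within their spread and 170 did not. The late differentiation call of each treatment held in 30 of 32 alternatives that gave a value, lost only with the estimated correlation and fry. For all values below the cause was not tested, except that fewer genes or arrays are tested where a filter or an omission is named.

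Quantile normalization gave 1 list for EphB2-Fc against untreated, 5 for EphB2-Fc against EFNA4-Fc, 8 genes for EFNA4-Fc late and 1 for EFNA4-Fc late minus early. Centred arrays gave 4 lists for EphB2-Fc early and 6 genes for EFNA4-Fc late. The largest pseudocount gave 11 genes for EFNA4-Fc late and, past 2-fold, 2, 8, 13 and 6 genes with EphB2-Fc and 1, 11, 24 and 11 with EFNA4-Fc at 1, 4, 24 and 48 h, and the 25th percentile gave 6 for EFNA4-Fc late. Without the level filter there were 9 lists for EphB2-Fc against untreated, 6 for EphB2-Fc early, 14 for EphB2-Fc late, 18 genes for EFNA4-Fc late and 3 for EFNA4-Fc late minus early. The filter at percentile 75 gave 0 lists for EphB2-Fc against untreated, 4 for EphB2-Fc early, 1 gene for EFNA4-Fc late, 1 for late minus early, 79 at 4 h and 1857 at 48 h. Without the trend EFNA4-Fc late had 1 gene and late minus early 7 lists.

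Array weights gave 488 genes and 0 lists for EphB2-Fc against untreated, 5 lists for EFNA4-Fc against untreated, 0 for EphB2-Fc against EFNA4-Fc, 4 for EphB2-Fc early, 26 genes for EFNA4-Fc late, 2 for late minus early, 1227 at 4 h and 2735 at 24 h. The mean of a gene's probe sets gave -0.0024 for CHP1 early with EphB2-Fc, 5 lists there and 7 lists for EFNA4-Fc late minus early. All probe sets gave 5 lists for EphB2-Fc against untreated, 5 for EphB2-Fc early, 7 for EFNA4-Fc early, 2431 genes at 24 h and 19 lists at 48 h. At adjusted p under 0.10 there were 7 lists for EphB2-Fc early, 19 genes for EFNA4-Fc late, 1 for late minus early and 452 at 4 h. Without the time block EphB2-Fc against untreated had 0 lists and EphB2-Fc against EFNA4-Fc 2. Camera with an estimated correlation called 0 lists in all 12 contrasts. Fry called 0 in EphB2-Fc against untreated, EFNA4-Fc against untreated, EphB2-Fc against EFNA4-Fc, EphB2-Fc early, late and late minus early, EFNA4-Fc early and late minus early, and at 4 h, 1 in EFNA4-Fc late, 10 at 24 h and 18 at 48 h.

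With the 18S covariate, EphB2-Fc against untreated had SDC4 at -0.28, COLGALT1 at -0.0726, TMEM259 at 0.10 and 14 lists. EphB2-Fc against EFNA4-Fc had CTTN at -0.10, FKBP9 at -0.0897, terminal differentiation at 0.0095, immediate early at -0.22, extracellular matrix at -0.11 and wound keratins at -0.0644. EphB2-Fc early had CTTN at -0.45, CHP1 at -0.26, terminal differentiation at -0.0280 and 11 lists, and EphB2-Fc late 11 lists. EFNA4-Fc early had 7 lists and cell cycle at -0.12. There were 16 genes at 4 h and 875 at 48 h, and r was 0.702. Without the 4 high-18S arrays there were 10 lists for EphB2-Fc against untreated, 1 gene and 15 lists for EFNA4-Fc against untreated, 39 genes for EphB2-Fc late, 73 for EFNA4-Fc late, 2 genes and 7 lists for EFNA4-Fc late minus early, and 22 genes at 4 h. EphB2-Fc against EFNA4-Fc then rested on the 48 h EphB2-Fc array alone. This contrast had CTTN at -0.0826, DSC1 at 0.0110, terminal differentiation at 0.0773 and extracellular matrix at -0.0622. Ribosome biogenesis in EFNA4-Fc early was 0.0388.

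Without 1 time or 1 array at a time, EphB2-Fc against untreated ran from 0 to 368 genes, 0 to 9 lists and a cell cycle mean of -0.38 to -0.0431. EFNA4-Fc against untreated ran from 5 to 18 lists and a basal layer mean of -0.10 to -0.0037. EphB2-Fc against EFNA4-Fc ran from 0 to 13 genes, 0 to 11 lists and a cell cycle mean of -0.34 to -0.0171. EphB2-Fc early ran from 0 to 6 genes and 0 to 6 lists. EphB2-Fc late ran from 0 to 5 genes, 2 to 14 lists, a cell cycle mean of -0.95 to -0.12 and an extracellular matrix mean of -0.43 to -0.0133. EphB2-Fc late minus early ran from 0 to 2 genes and 5 to 14 lists. EFNA4-Fc early ran from 0 to 4 genes, 2 to 10 lists, an EGFR mean of -0.29 to 0.0080 and a ribosome biogenesis mean of -0.26 to 0.0388. EFNA4-Fc late ran from 0 to 27 genes, with a basal layer mean of -0.28 to 0.0069, a cell cycle mean of -0.51 to 0.10 and an interferon mean of -0.0572 to 0.28. EFNA4-Fc late minus early ran from 0 to 2 genes, 6 to 14 lists, a desmosome mean of -0.0055 to 0.24 and a cell cycle mean of -0.65 to -0.0374. At 4 h 8 to 598 genes passed and at 24 h 905 to 1677, and r ran from 0.341 to 0.729.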

Other observations

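The correlations with the course of time in culture without the 5 lists, and the comparison of the count of genes without the 1 h time, were chosen after the results were seen.

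The lists below were not called at 48 h, and single members passed in either direction (3 arrays a time, limma). The small heat shock proteins CRYAB and HSPB8 rose by 4.53 ± 0.34 and 2.49 ± 0.22 (log2, SE), while of 21 heat shock genes 5 rose and 10 fell (camera adjusted p = 0.206). The aldo-keto reductases AKR1C1 and AKR1C3 rose by 1.96 ± 0.20 and 2.54 ± 0.28, and of 25 NRF2 genes 6 rose and 11 fell (adjusted p = 0.938). KRT16, a keratin of stressed epidermis, rose by 2.83 ± 0.21 and TIMP1, an inhibitor of metalloproteases, by 1.91 ± 0.13. The keratins of simple epithelia KRT18 and KRT7 fell by 1.55 and 2.25, and vimentin (VIM), the intermediate filament of mesenchymal and cultured cells, by 1.53. Of 17 wound keratin genes 6 rose and 7 fell (adjusted p = 0.885).

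In the basal layer list 6 of 17 genes rose and 6 fell at 48 h (adjusted p = 0.885), with BCAM at 1.29 ± 0.16 and the hemidesmosome integrin ITGB4 at -1.09 ± 0.12. Single genes of other lists that were not called also fell: the Wnt inhibitor DKK1 by 2.10, the MAPK-induced transcription factor ETV5 by 2.34, HMGA2 by 1.86 and the urokinase gene PLAU by 1.09. Of 31 interferon response genes 9 rose and 11 fell, with IFIT3 at -1.61 ± 0.15 and IRF1 at -1.34 ± 0.14 (adjusted p = 0.743). Proteasome genes fell in 14 of 27 and rose in 1 (mean -0.17, adjusted p = 0.0676), and cholesterol genes fell in 8 of 19 and rose in 1 (mean -0.23, adjusted p = 0.153). TGF-beta targets fell in 11 of 20 and rose in 4 (mean -0.32, adjusted p = 0.101).

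Across genes, the late effect of each treatment correlated with the 48 h minus 1 h change of the other treatment. The r of the late EphB2-Fc effect with the EFNA4-Fc 48 h minus 1 h change was 0.487, and without the members of 5 lists of differentiation and proliferation it was 0.453. For the late EFNA4-Fc effect with the EphB2-Fc change the values were 0.511 and 0.462. The early effects gave -0.225 and 0.179. Without the 5 lists 6695 of 6801 genes remained, while 2945 genes changed at 48 h, so this omission tests little. Each 48 h minus 1 h change also holds that treatment's own 48 h effect. A response shared by both agents would give a positive r as well. These are correlations across genes, which are not independent replicates, and their value of 0.487 is consistent with treated cultures that are further along, a hypothesis only.

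Fibroblast markers were abundant in part: VIM had a mean level of 12.01 and MFAP5 of 11.43, where 10.04 is the 90th percentile of the genes tested. They moved apart with time, as TAGLN stood at 4.05 and DCN at 1.98 at 48 h and VIM at -1.53 and POSTN at -1.35. Their late values were -0.59 and -1.11 for VIM and POSTN with EphB2-Fc. The fibroblast list, the only list of another cell type with enough members to test, was not called in any contrast.

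The genes of the same sign at all 4 times made up 11.3% with EphB2-Fc, 11.4% with EFNA4-Fc and 10.9% between the treatments, where 12.5% is the share by chance. Of the 368 genes that passed for EphB2-Fc without the 1 h time, the 278 that were lower had a median of 0.37 at 1 h and the 90 that were higher a median of -0.30.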
